A study of Mus musculus with 12 samples.

How the data were processed

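The data are Cy3 signals from 12 Agilent 1-colour expression arrays, 3 for each of 4 groups. B cells had been isolated from spleens of 9-week-old female BALB/c mice, wild type or STAT6 knockout, and the cells were stimulated for 4 days with an antibody to CD40 and lipopolysaccharide, with or without IL-4. The labels give RNA integrity numbers of 9.6 to 9.9 and 100 ng of RNA per labelling. Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.3.1 and hold the processed signal of each spot as an intensity, background subtracted and detrended within the array, with a surrogate for spots not above background and no normalisation between arrays. They also hold the mean and background intensity and flags for each spot. The authors also deposited a file of values, with a single one per gene name and array, which its first line describes as background subtracted, quantile normalised and on the log2 scale. That file was used as an alternative.

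The main values start from the processed signal. It was put on the log2 scale, and the 75th percentile of the array over its 59305 non-control spots (296 to 356 in intensity) was subtracted. Between 122 and 196 spots per array with outlier flags were left out, and spots of a probe were averaged, which gave 55681 probes with 34650 gene names. A probe was kept if it was well above background on all 3 arrays of at least 1 group (22940 probes), with at least 2 values in every group. The kept probe with the highest mean stood for its gene, and 16497 genes were tested, of which 4606 had more than 1 kept probe. Positions are those of the files (mm9). RefSeq accessions of 28026 probes, of 29796 with one, matched the reference annotation, where 1651 of them carry another symbol today. Signals replaced by a surrogate can make folds of dim genes too large or too small. For a gene not well above background on any array of the dimmer group, a bound is given instead, with signals in the dim group raised to at least the lowest signal well above background on that array.

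Group means were fitted with limma 3.58.1 in R 4.3.3 (with data.table version 1.17.8 and jsonlite 2.0.0) over all 12 arrays, and 5 contrasts were tested: IL-4 in each genotype, their difference (wild-type response minus knockout response), and knockout minus wild type without and with IL-4. P-values were adjusted by Benjamini-Hochberg over the genes tested within each contrast. The threshold was an adjusted p under 0.05 with an absolute log2 change of at least 1. For members of gene lists, rose, fell, higher and lower mean an adjusted p under 0.05 at any size. The contrasts share arrays, except that the IL-4 responses of the genotypes share none. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

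The scanner headers place the arrays on 2 slides. A model with slide as a block was fitted beside the main one for every contrast. It compares within slides and rests on knockout controls 1 and 2 against control 3 wherever groups lie on different slides. Replicate numbers were not used to pair samples in the main model.

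Before the data were examined, 28 gene lists were fixed and tested with camera against all other genes, with a preset correlation of 0.01 and again with a correlation estimated from the data. Adjustment was over the lists of a contrast with at least 3 members tested. With an estimated correlation no list passed in any contrast. 2 further lists, for hypoxia and for the ATF4 response, were written after the data had been seen, as was the naming of immunoglobulin constant regions from the descriptions on the array, which added members to fixed lists. The genes named were also chosen by a rule fixed beforehand. It takes fixed genes (Stat6, Fcer2a, Il4ra, Ighg1 and Ighe among them), then the 10 genes with the largest change in each direction (5 for the knockout response and the interaction) among genes past the threshold with symbols, well above background in the compared groups (for the interaction, in at least 3 of the 4) and without overlap between arrays. It adds up to 5 genes per direction by the largest bound, and up to 4 members of each list with the smallest adjusted p. A few genes that the rule names are not reported here. Cd3d, the members of the 2 added lists and most genes named from chromosomes 1 and 10 fall outside that rule and were chosen after their values had been seen.

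The test of neighbours counted genes within 10 Mb of Stat6 (and 5 and 20 Mb) by Fisher's exact test. The scan of all chromosomes in bins of 10 Mb was added after the data had been seen, and a version with both genotype contrasts and a smaller fold limit was looked at first. It was later repeated with slide as a block. Results were recomputed with quantile and median scaling, normexp background correction (offset 50), no filter and a stricter filter on dim probes, the mean of all probes, no fold minimum, other variance settings, only the compared arrays, slide and replicate blocks, each array left out in turn, and the authors' values. The counts of genes were also compared with those of other groupings of the same arrays. The procedure was tested on simulated data with 200 changed genes. For the wild-type contrast, 51 of 67 genes changed 1.5-fold passed the adjusted p, as did 59 of 67 changed 2-fold and 61 of 66 changed 4-fold, and 8 of 16297 unchanged genes did. With no gene changed, 0 passed in the knockout response and in the comparison of controls. The simulated noise was independent between genes and held no slide or culture effect. False calls from such shared effects are therefore not covered.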

Results

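Gene expression was measured on 1-colour microarrays in B cells from the spleens of female BALB/c mice, either wild type or lacking STAT6, the transcription factor activated by the IL-4 receptor. All cells had been stimulated for 4 days with an antibody to CD40 (10 µg/ml) and lipopolysaccharide (2 µg/ml), so the controls without IL-4 are activated B cells. IL-4 was present at 25 ng/ml or absent. The 12 arrays form 4 groups of 3: wild-type control, wild-type IL-4, knockout control and knockout IL-4. Each array gave values for 59305 non-control spots, of which 40.7% to 44.0% were well above background, and no spot was saturated. The number of arrays, 3 per group, limits the precision of every value. Arrays of a group correlated at r = 0.994 to 0.998 across the 16497 genes tested, where genes are not independent replicates, and the median SD of a gene within a group was 0.07 to 0.11 on the log2 scale. The first principal component (65.8% of the variance) placed the wild-type IL-4 arrays between 77.2 and 79.0 and the other arrays between -32.5 and -14.6. The second (13.9%) placed the knockout IL-4 arrays between 33.8 and 36.8 and the others between -20.0 and -4.91. The arrays came from 2 slides. Slide 1 held all wild-type arrays and knockout controls 1 and 2, and slide 2 held knockout control 3 and the knockout IL-4 arrays, so many of the results that involve the knockout are also given with slide as a block. The labels call the samples triplicates without stating whether these came from separate animals, so the p-values may measure only the spread between these samples.

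The first comparison asks which genes IL-4 changed in cells that have STAT6. The immunoglobulin constant regions moved apart. Ighg1, which encodes the IgG1 heavy chain, was 6.57-fold higher with IL-4 (log2 change 2.72 ± 0.07 SE, 3 arrays per group) and Ighe, for the IgE heavy chain, was 6.20-fold higher (2.63 ± 0.10). Ighg2b was 53.7-fold lower and Ighg3 7.35-fold lower, and Ighm, for the IgM heavy chain, was 2.11-fold lower. Fcer2a, the low-affinity IgE receptor CD23, rose 3.04-fold and Il4ra, a chain of the IL-4 receptor, rose 7.63-fold. In all, 2089 of 16497 genes passed an adjusted p under 0.05 with at least a 2-fold change (limma), 943 of them higher and 1146 lower, and 9428 passed the adjusted p alone. In 2080 of the 2089 the arrays of the groups did not overlap, which chance gives for 10% of unchanged genes but which choosing genes on the same arrays favours here. Adjusted p was 6.24e-10 for Ighg1, 6.34e-09 for Ighe, 1.85e-09 for Fcer2a and 5.54e-07 for Il4ra, while Stat6 itself differed by 0.18 ± 0.08 (adjusted p = 0.0733). The constant regions are listed under transcript identifiers (ENSMUST00000103420 for Ighg1 and ENSMUST00000137336 for Ighe), and their symbols were read from the descriptions on the array. Subclass sequences resemble one another, so a probe may read more than one of them, and a second Ighg1 probe rose 2.15-fold.

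Among genes with symbols, well above background in both groups and without overlap between arrays, the largest rises were those of Htr7, a serotonin receptor (228-fold), Cish and Socs2, feedback inhibitors of cytokine signalling (127-fold and 62.3-fold), and Il5ra, the IL-5 receptor alpha chain (69.3-fold). Oit3 (37.6-fold), Gnb4, a G protein beta subunit (27.6-fold), Plcd1, a phospholipase C (27.0-fold), B4galt4, a galactosyltransferase (24.3-fold), Serpina3f, a serpin (24.2-fold), and Atp11a, a phospholipid flippase (21.9-fold), followed. The largest falls among them were those of Ccr6, a chemokine receptor (243-fold lower), Igj, the joining chain of polymeric immunoglobulin (56.5-fold), Nid1, a basement membrane protein (38.0-fold), and Fcrla, an Fc receptor-like protein of B cells (34.5-fold). Slc6a13, Pla1a, Anxa1, Snx22 and Ccl5 fell 28.6-, 25.0-, 20.6-, 20.3- and 18.3-fold. For genes not well above background on any array of the lower group only a bound can be given. Thy1, a surface glycoprotein best known from T cells, was at least 1530-fold higher with IL-4, Gzma, a granzyme, at least 70.8-fold, Vsig2 at least 43.8-fold, Rai14 at least 33.1-fold and Nes, an intermediate filament protein, at least 29.3-fold. Csf2, the cytokine GM-CSF, was at least 37.4-fold lower, Itln1 at least 34.0-fold, Ccdc67 at least 27.1-fold, Cd5l at least 23.8-fold and Elovl7, a fatty acid elongase, at least 18.8-fold.

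Of 18 known IL-4 and STAT6 target genes of B cells tested, 13 rose and 1 fell in wild-type cells, with the same counts adjusted over the list alone. Nfil3, a transcription factor, was 12.1-fold higher. The list as a whole moved up against other genes (camera with a preset correlation of 0.01, adjusted p = 9.89e-06), a call lost with an estimated correlation (adjusted p = 0.212). Interferon response genes moved the other way: 30 of 31 fell and 0 rose, with the same counts adjusted over the list alone. Their median log2 change was -1.32, and Ifit1, Ifih1, Rtp4 and Mx2, antiviral effectors and sensors, were 6.14-, 2.49-, 10.6- and 8.17-fold lower. The shift had an adjusted p of 3.10e-13, and of 0.0730 with an estimated correlation. Cholesterol biosynthesis genes fell in 18 of 19 cases, mostly by less than 2-fold, with Cyp51 2.19-fold and Mvd 1.82-fold lower (adjusted p = 8.04e-07, and 0.403 with an estimated correlation; 18 fell adjusted over the list alone). Of 21 genes of mature B cell identity, 15 fell and 4 rose (the same adjusted over the list alone; adjusted p = 4.10e-04, and 0.170 with an estimated correlation). Fcrla, Id3, Cr2, the complement receptor CD21, and Bank1 fell most clearly, by 34.5-, 17.7-, 10.9- and 5.39-fold. Cell cycle genes rose in 16 of 31 cases and fell in 2, also adjusted over the list alone, by small amounts apart from Ccnd2, cyclin D2, at 2.49-fold (adjusted p = 0.0216, and 0.626 with an estimated correlation).

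Other groups had members going both ways in wild-type cells, and their camera tests did not pass. By the adjusted p alone, 4348 of all 16497 genes rose and 5080 fell in wild type, and the list counts are to be read against these. Among costimulatory and inhibitory molecules, Icosl and Tnfrsf13b were 10.8-fold and 2.21-fold lower, whereas Slamf1 and Havcr1 were 4.38-fold and 5.44-fold higher (5 of 18 rose and 9 fell, 6 and 9 adjusted over the list alone; adjusted p = 0.442). Plasma cell genes rose in 6 and fell in 6 of 15 cases, also adjusted over the list alone. Prdm1, the regulator of plasma cell differentiation, and Derl3 were 7.03-fold and 8.42-fold lower (list adjusted p = 0.689). Of 29 cytokine receptors and JAK-STAT regulators, 16 rose and 9 fell, also adjusted over the list alone, with Socs1 4.24-fold higher and Il9r 4.29-fold lower (adjusted p = 0.0904). MHC class II genes rose in 5 and fell in 3 of 14 cases, also adjusted over the list alone, with H2-DMa 1.87-fold higher and H2-Eb2 1.74-fold lower (adjusted p = 0.442). Bcl6, the germinal centre repressor, was 2.20-fold higher.

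Markers of other cell types also split. Of 10 T cell markers tested, Thy1 and Cd3d rose, the latter by 0.73 on the log2 scale, while Cd5, Cd6 and Cd2 fell 4.57-, 3.27- and 2.19-fold (adjusted p of the list 0.666; 2 rose and 3 fell adjusted over the list alone; median -0.15, test downward, but mean 0.63 because of Thy1). Of 4 markers of NK and cytotoxic cells, Gzma and Gzmb (at least 3.01-fold) rose, and Prf1 and Nkg7 fell (list adjusted p = 0.504; 2 and 2 adjusted over the list alone). Of 6 macrophage markers, Mpeg1 fell 13.2-fold and Sirpa rose 4.19-fold (list adjusted p = 0.718; 2 rose and 2 fell adjusted over the list alone; median 0.03, but mean -0.36 and test downward). Of 7 dendritic cell markers, Batf3 and Zbtb46 rose 5.72-fold and 2.55-fold and Flt3 fell 3.13-fold (list adjusted p = 0.418; 4 rose and 2 fell adjusted over the list alone). Kit, the receptor tyrosine kinase of mast cells, was the only mast cell marker tested and was at least 5.04-fold lower.

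**Figure D1:**
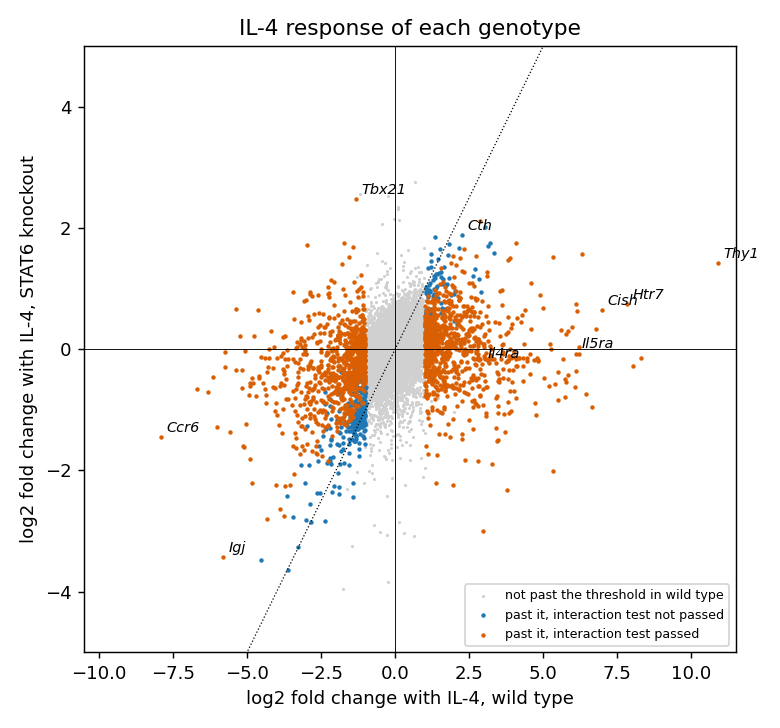
Each point is a gene, with its log2 fold change with IL-4 in wild-type cells on the horizontal axis and in knockout cells on the vertical axis (3 arrays per group). Orange points (1681 of the 2089 past the threshold in wild type) also passed the interaction test, blue points did not, and the dotted line marks equal responses.

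The next comparison asks what IL-4 changed in cells without STAT6. Without STAT6, Ighg1 differed by 0.13 ± 0.07 with IL-4 (log2, SE; adjusted p = 0.185) by its brighter probe and fell by 0.27 by its second probe (adjusted p over probes 0.00464). Ighe was 2.51-fold lower (adjusted p = 6.22e-06). Fcer2a rose 1.55-fold, and Il4ra differed by -0.24 ± 0.20 (adjusted p = 0.355). Several genes that act in plasma cells were lower, with Igj 10.8-fold, Prdm1 3.22-fold, Derl3 3.17-fold and Xbp1, a regulator of secretory capacity, 1.87-fold lower. Among genes with symbols, well above background in both groups and without overlap between arrays, the largest rises were those of Tbx21, the transcription factor T-bet (5.56-fold), Bspry (4.38-fold), Cox6a2, a subunit of cytochrome oxidase (4.34-fold), Irg1, which makes itaconate (4.17-fold), and Cth, an enzyme of cysteine synthesis (3.67-fold). The largest falls among them were those of Rgs11 (15.6-fold) and Mgarp (14.3-fold), whose SD among knockout IL-4 arrays was 2.39 and 2.53, and of Igj, Prg2 (6.79-fold) and Pygl, glycogen phosphorylase of the liver type (5.36-fold). Rgs11 and Mgarp were also higher in knockout than in wild-type controls, so their falls start from a raised level. That difference between controls did not pass with slide as a block. By bounds, Il2 was at least 3.20-fold higher with IL-4, and Cdh16 and Il18r1 were at least 6.18-fold and 5.17-fold lower.

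In total, 580 of 16497 genes passed the threshold in knockout cells, 130 higher and 450 lower. The balance was the other way among the 6969 that passed the adjusted p alone, with 4539 higher and 2430 lower. With slide as a block, where the knockout IL-4 arrays are set against knockout control 3 alone, 630 genes passed (98 higher and 532 lower) and 406 of the 580 remained with the same sign. Within slide 2 the log2 change was -1.47 for Ighe, 0.70 for Fcer2a, -3.12 for Igj and 2.11 for Tbx21, each past the test, and 0.04 for Ighg1 (adjusted p = 0.795). Il4ra was -0.76 there and passed (adjusted p = 0.00878), and Il2 lost its call (adjusted p = 0.200). Scaling by the median of each array in place of the 75th percentile raised the share of called genes that were higher from 22.4% to 43.0% and moved the median of all genes from 0.05 to 0.20 on the log2 scale.

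Of 31 cell cycle genes, 28 rose in knockout cells with IL-4 and 0 fell, also adjusted over the list alone. Bub1b, Top2a, Foxm1 and Kif11, which act in mitosis, were 1.87-, 1.57-, 1.78- and 1.66-fold higher. The list median was 0.52, and 0.56 within slide 2 (camera adjusted p = 5.71e-09, and 0.350 with an estimated correlation). MHC class II genes fell in 10 of 14 cases and rose in 0 (1 adjusted over the list alone), with H2-Eb2 1.72-fold and H2-DMb1 1.60-fold lower (median -0.40, and -0.40 within slide 2; adjusted p = 3.00e-06, and 0.167 with an estimated correlation). Plasma cell genes fell in 9 of 15 cases and rose in 2 (10 and 2 adjusted over the list alone; median -0.41, and -0.40 within slide 2; adjusted p = 5.52e-05, and 0.350 with an estimated correlation). Of 9 immunoglobulin constant region and switching genes, 7 fell and 0 rose (7 and 1 adjusted over the list alone; 4 and 1 within slide 2). Ighm was 1.84-fold and Ighg3 1.87-fold lower (adjusted p of the list 4.61e-04, and 0.167 with an estimated correlation). Glycolysis genes fell in 11 of 19 cases and rose in 0 (16 and 0 adjusted over the list alone), with Aldoc and Pfkl 2.67-fold and 2.66-fold lower. Their median was -0.80, and -1.08 within slide 2 (adjusted p = 3.69e-05, and 0.444 with an estimated correlation), and their mean over the list was -0.54, -0.25 and 0.68 in knockout IL-4 arrays 1, 2 and 3. Interferon response genes, which fell in wild-type cells, rose in 15 and fell in 3 of 31 cases here (16 and 3 adjusted over the list alone; adjusted p = 0.0893), with Isg15 2.00-fold and Oasl1 1.95-fold higher. Cholesterol biosynthesis genes fell in 7 and rose in 2 of 19 cases (camera adjusted p = 0.0391, and 0.490 with an estimated correlation). Their median was -0.10, and -0.02 within slide 2. Of 18 known IL-4 and STAT6 target genes, 10 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.584). Among these Bcl2l1, a survival factor, rose 1.90-fold, and Il4i1, an amino acid oxidase, fell by 0.59 on the log2 scale. Within slide 2, 26 cell cycle genes rose, 9 MHC class II, 8 plasma cell and 9 glycolysis genes fell, 11 interferon response genes rose and 2 fell, and 9 known target genes rose and 6 fell. In other groups Il6 rose 2.52-fold and Cd80 2.00-fold, and Cd5 and Fcrla fell 3.59-fold and 3.05-fold.

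The interaction asks, gene by gene, whether the IL-4 response differed between the genotypes. Responses are compared as signed log2 changes, so a lower wild-type response can be a larger fall in wild type. Thy1 responded more in wild-type cells by 9.49 ± 0.24 on the log2 scale (SE), Htr7 by 7.09 ± 0.26, Cish by 6.35 ± 0.21, Il5ra by 6.19 ± 0.14 and Ndrg2 by 6.09 ± 0.92. In the other direction the wild-type response was lower for Ccr6 by -6.47 ± 0.12, Csf2 by -6.06 ± 0.14, Cd5l by -5.71 ± 0.45, Itln1 by -5.70 ± 0.42 and Nid1 by -5.47 ± 0.12. Several of these were near background in 1 group, so the size of their difference is uncertain. Ndrg2 was also higher in knockout than in wild-type controls, which adds to its difference. The difference was 3.96 ± 0.14 for Ighe, 3.17 ± 0.28 for Il4ra, 2.59 ± 0.10 for Ighg1 and 0.97 ± 0.07 for Fcer2a, with adjusted p of 1.33e-08, 1.01e-05, 2.65e-08 and 2.33e-06. With slide as a block these were 4.10, 3.69, 2.68 and 0.90. By the second Ighg1 probe the difference was 1.38 (adjusted p over probes 7.01e-07). For Stat6 it was not detectable (adjusted p = 0.993).

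In all, 1756 genes passed the threshold for the interaction, 926 higher and 830 lower, and 1965 did so with slide as a block, of which 1598 were shared. By the adjusted p alone 7388 genes passed the interaction in the main model, 2712 higher and 4676 lower, so the balance depends on the fold minimum. Of the 2089 genes past the threshold in wild type, 1681 (80.5%) also passed the interaction test in the same direction, 89.6% of those that rose and 72.9% of those that fell. The share was 78.8% with slide as a block, 68.3% with no filter on dim probes and 89.5% with normexp background correction. The genes were chosen on their wild-type change, which is part of the interaction, so the choice itself favours a high share. Both genotypes changed 63 genes upward, against 7.43 for independent lists, and 264 genes downward, against 31.3. With slide as a block these counts were 36 and 223. Among the genes that rose in wild type the median ratio of knockout to wild-type log2 change was 0.07, and among those that fell it was 0.26. Choosing genes on a large wild-type change also tends to make these ratios smaller. Under scaling by array medians the share of interaction genes with a higher wild-type response fell from 52.7% to 41.5%, while the median of all genes went from -0.10 to -0.23.

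Interferon response genes had a lower wild-type response in 28 of 31 cases and a higher one in 0, also adjusted over the list alone. Ifit1, Ifih1, Oasl1 and Rtp4 differed by -3.52, -1.95, -2.25 and -3.91, and the list median was -1.72, and -1.68 with slide as a block (camera adjusted p = 2.30e-14, and 0.0574 with an estimated correlation). Known IL-4 and STAT6 target genes had a higher wild-type response in 13 of 18 cases and a lower one in 3, also adjusted over the list alone (adjusted p = 1.42e-06, and 0.144 with an estimated correlation). MHC class II genes had a higher wild-type response in 9 of 14 cases and a lower one in 1, also adjusted over the list alone, led by H2-DMa at 1.31 and H2-DMb1 at 1.16 (camera adjusted p = 8.50e-05, and 0.188 with an estimated correlation). Their median log2 change with IL-4 was 0.11 in wild type and -0.40 in the knockout. The response of mature B cell genes was lower in wild type for 16 of 21 and higher for 2 (17 and 2 adjusted over the list alone; adjusted p = 5.23e-05, and 0.0984 with an estimated correlation), as for Id3 at -3.83 and Cr2 at -3.29. That of cholesterol biosynthesis genes was lower for 16 of 19 and higher for 0, also adjusted over the list alone (camera adjusted p = 3.57e-05, and 0.378 with an estimated correlation). Both lists fell more in wild type. Median log2 changes in wild type and knockout were -0.59 and -0.04 for mature B cell genes and -0.60 and -0.10 for cholesterol genes. Cell cycle genes had a lower wild-type response in 13 of 31 cases and a higher one in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.0254, and 0.629 with an estimated correlation). Glycolysis genes, raised in knockout controls, had a higher wild-type response in 4 of 19 cases and a lower one in 0 (camera adjusted p = 0.0127, and 0.629 with an estimated correlation). The lists of the unfolded protein response and of cytokine receptors also moved up (camera adjusted p = 0.0254 each, and 0.488 and 0.408 with an estimated correlation). The counts of lower and higher responses with slide as a block were 28 and 0 for interferon, 3 and 13 for known target, 1 and 9 for MHC class II, 15 and 2 for mature B cell, 15 and 0 for cholesterol and 16 and 2 for cell cycle genes. Xbp1 and Cd28, a costimulatory receptor, differed by 1.77 and 3.28, and Cd80 by -2.76.

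**Figure D2:**
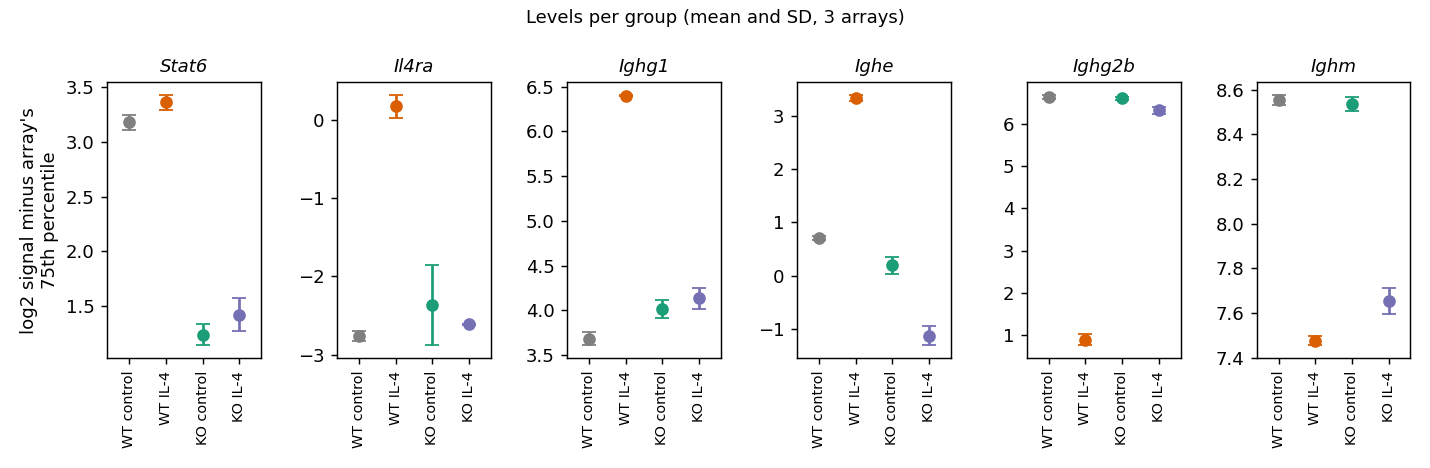
Levels of Stat6, Il4ra and immunoglobulin constant region genes in the 4 groups, as log2 signal minus the 75th percentile of the array (points are means, bars are SD, 3 arrays per group). Ighg1 rose from 3.68 to 6.40 with IL-4 in wild type and stayed between 4.01 and 4.13 in the knockout, and Stat6 was 1.24 in knockout controls and 3.18 in wild-type controls.

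The comparison of the genotypes without IL-4 asks how knockout and wild-type activated B cells differed when they had not been given IL-4. Stat6 was 3.84-fold lower in knockout controls (log2 level 1.24 ± 0.10 against 3.18 ± 0.07, SD, n = 3 each). Its probe A_52_P114494 lies on chromosome 10, from 127097689 to 127097748 in mm9, and the other kept probes were 1.84-fold and 4.84-fold lower. All were still above background in knockout arrays. Lower in knockout controls were also Ctse, the protease cathepsin E (8.49-fold), Arl2bp (6.62-fold), Xrcc6bp1 (4.44-fold), Ren2, a renin (3.75-fold), Ptprv (2.78-fold), Parm1 (2.73-fold), Ipo9, an importin (2.70-fold), H2-Q5 (2.57-fold) and Saa3 (2.55-fold). Higher were Rgs11 (19.6-fold), Mgarp (17.3-fold), P4ha2, a collagen prolyl hydroxylase (14.7-fold), Egln3, an oxygen-sensing prolyl hydroxylase (9.10-fold), Cox7a1 (7.48-fold), Dnah8, a dynein chain (6.80-fold), Ndrg2 (6.51-fold), Fam71f2 (6.10-fold) and Daf2, a complement regulator (6.02-fold). Of these genes, Ctse, Ptprv, Ipo9 and Daf2 lie on chromosome 1 and Xrcc6bp1 near Stat6, in regions where differing genes lay close together. A chromosome segment from another strain is weighed for these regions below, so such differences need not come from loss of STAT6.

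The adjusted p was 1.03e-06 for Stat6, 1.21e-09 for Dnah8, 1.17e-09 for Arl2bp and 4.22e-08 for Ctse, and it was 0.0263 for Rgs11 and 0.0410 for P4ha2, whose SD among knockout controls was 1.02 and 1.21. Ighg1 was 1.26-fold higher (adjusted p = 0.0243; second probe 0.09 on the log2 scale, adjusted p over probes 0.306) and Ighe 1.43-fold lower (adjusted p = 0.0153), while Il4ra differed by 0.39 ± 0.20. In total 194 genes passed the threshold, 138 higher and 56 lower, all with arrays that did not overlap. The balance was the other way among the 1929 that passed the adjusted p alone, with 780 higher and 1149 lower. Within slide 1, which leaves out knockout control 3, 81 genes passed (32 higher and 49 lower) and 67 of the 194 remained. Within slide 1, Stat6 (-1.97), Dnah8 (2.76), Daf2 (2.64), Arl2bp (-2.74) and Ctse (-3.04) passed, and Rgs11 (3.92), Mgarp (3.74), P4ha2 (3.39), Egln3 (2.74), Cox7a1 (2.49), Ndrg2 (2.21), Fam71f2 (2.26) and Ighg1 (0.28) did not. The count depended on single arrays: it was 103, 89 and 77 without wild-type control 1, 2 and 3, and 331, 80 and 98 without knockout control 1, 2 and 3. Of the genes called, 71.1% were higher, and 47.2% were with scaling by array medians, which shifted the median of all genes from -0.04 to -0.23.

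Glycolysis genes were higher in knockout controls in 16 of 19 cases and lower in 0 (18 and 0 adjusted over the list alone). Pgk1, Pkm, Eno1 and Hk2 were 2.33-, 2.35-, 2.03- and 1.76-fold higher. Within slide 1 only 1 of the 19 passed. The list median was 1.06, and 0.90 within slide 1 (camera adjusted p = 1.40e-12, and 0.474 with an estimated correlation). The mean of the list was 0.45, 0.88 and 1.03 in knockout controls 1, 2 and 3 and between -0.36 and -0.23 in wild-type controls. Erythroid genes were higher in 4 of 6 cases (5 adjusted over the list alone), with the globins Hba-a2 and Hbb-b2 1.63-fold and 1.75-fold higher (median 0.74, and 0.73 within slide 1, where 1 passed; adjusted p = 0.00148, and 0.423 with an estimated correlation). Of 31 interferon response genes 9 were lower and 1 was higher (11 and 2 adjusted over the list alone, 4 and 0 within slide 1; adjusted p = 0.377), with Ifit1 1.46-fold lower. Known IL-4 and STAT6 target genes were higher in 2 and lower in 3 of 18 cases, also adjusted over the list alone, and in 0 and 1 within slide 1 (adjusted p = 0.936). Among single genes of other lists, Socs3, an inhibitor of cytokine signalling, was 2.08-fold higher, Vegfa, an angiogenic factor, 2.30-fold higher and Icosl 1.49-fold lower.

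**Figure D3:**
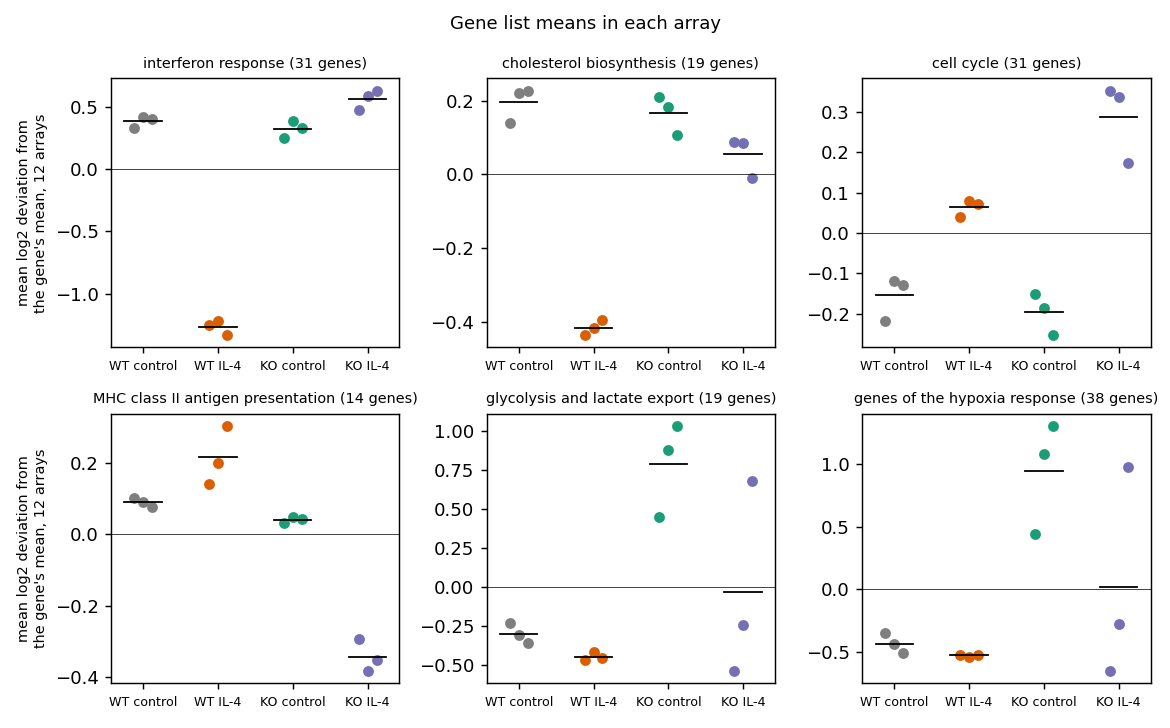
Mean of each gene list in each array, as the log2 deviation of its genes from their mean over the 12 arrays (points are arrays, black lines are group means). Interferon response genes were lowest in the wild-type IL-4 arrays (-1.33 to -1.22), and glycolysis genes were highest in knockout controls (0.45 to 1.03) and in knockout IL-4 array 3 (0.68).

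Genes near Stat6 differed more often between the genotypes than genes elsewhere. Within 10 Mb of Stat6 on chromosome 10 (mm9), and without Stat6 itself, 30 of 122 genes (24.6%) passed the adjusted p without IL-4, against 1880 of 16200 (11.6%) elsewhere, an odds ratio of 2.48 (Fisher exact p = 8.95e-05, two-sided). With slide as a block it was 11 of 122 against 396 of 16200 (odds ratio 3.95, exact p = 2.38e-04). In the comparison with IL-4 the share was 54.9% against 51.1% (odds ratio 1.17, exact p = 0.414).

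**Figure D4:**
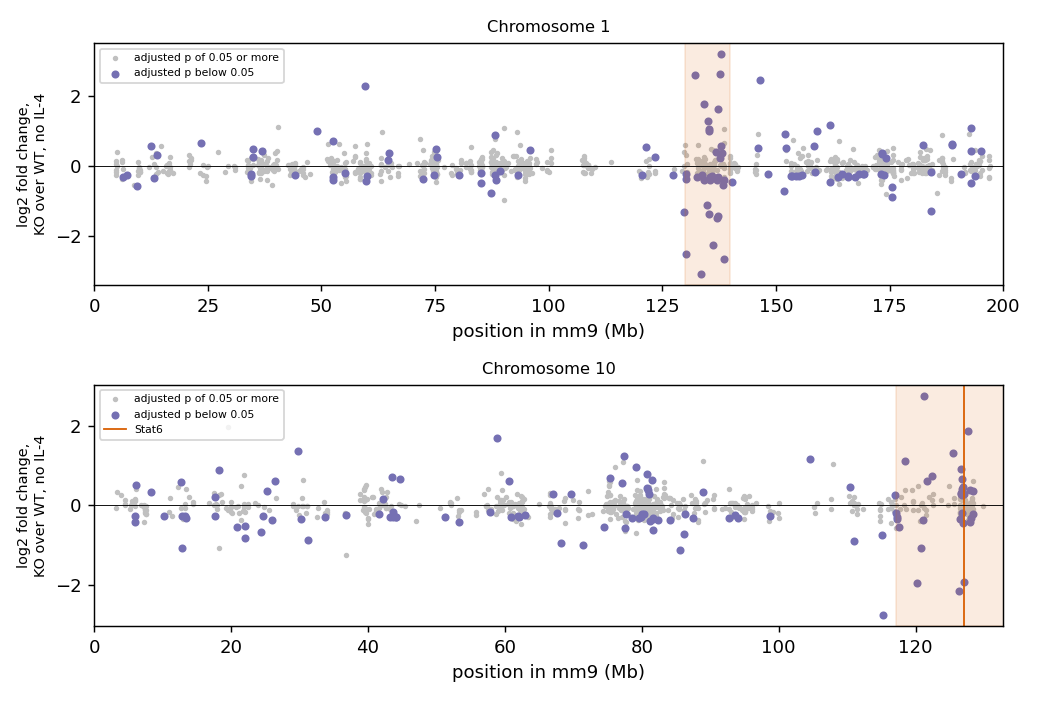
Log2 fold change of knockout over wild-type controls by position in mm9 on chromosomes 1 and 10 (points are genes, purple where the adjusted p was under 0.05, orange line at Stat6). Shading marks 10 Mb to either side of Stat6 on chromosome 10 and the bin from 130 to 140 Mb on chromosome 1, where 32 of 101 genes passed.

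The last comparison sets the genotypes side by side in the presence of IL-4. In knockout cells Thy1 was 345-fold lower, Htr7 235-fold, Il5ra 87.8-fold, Plcd1 52.9-fold, Cish 52.6-fold, Socs2 51.4-fold, Gnb4 31.1-fold, Oit3 31.0-fold, Vsig2 27.7-fold and Gprin3 26.3-fold. Ighe was 22.2-fold lower, Il4ra 6.90-fold, Ighg1 4.80-fold (2.44-fold by its second probe), Stat6 3.84-fold and Fcer2a 2.26-fold. Higher in knockout cells were Ccr6 (98.2-fold), Nid1 (38.3-fold), Pla1a, a phospholipase (38.1-fold), Lgals3bp, a galectin-binding protein (19.4-fold), Slc6a13 (15.3-fold), Rtp4 (14.6-fold), Ccl5, a chemokine (14.4-fold), Usp18, which removes ISG15 from proteins (13.2-fold), and Car2, a carbonic anhydrase (13.0-fold). By bounds, Gzma was at least 81.7-fold lower, Pros1 63.6-fold, Rai14 38.2-fold, Nes 33.8-fold and Ccr4 27.0-fold, and Csf2 was at least 39.1-fold higher.

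The adjusted p was 2.04e-10 for Ighe, 2.44e-09 for Ighg1, 1.84e-08 for Stat6 and 7.89e-12 for Ccr6. With IL-4, 1597 genes passed the threshold, 764 higher in the knockout and 833 lower, and 1702 with slide as a block (718 higher and 984 lower), of which 1338 were shared. By the adjusted p alone 8431 genes passed in the main model, 4919 higher in the knockout and 3512 lower, so the balance depends on the fold minimum. With slide as a block the log2 difference was -4.68 for Ighe, -2.40 for Ighg1, -3.56 for Il4ra, -7.92 for Thy1 and 6.78 for Ccr6. The knockout IL-4 arrays all lie on slide 2 and the wild-type IL-4 arrays on slide 1, so this blocked value rests on the slide difference seen among knockout controls alone.

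Interferon response genes were higher in knockout than in wild-type cells with IL-4 in 29 of 31 cases and lower in 0 (30 and 0 adjusted over the list alone), by a median of 1.74, and 1.56 with slide as a block (camera adjusted p = 1.38e-14, and 0.0548 with an estimated correlation). Ifit1 was 7.82-fold and Ifih1 3.47-fold higher. Mature B cell genes were higher in 16 of 21 cases and lower in 3, also adjusted over the list alone (adjusted p = 7.77e-05, and 0.115 with an estimated correlation), as Fcrla 11.6-fold, Id3 12.4-fold and Cr2 7.81-fold. Cholesterol biosynthesis genes were higher in 15 of 19 cases and lower in 0, also adjusted over the list alone, with Mvd 1.87-fold higher (adjusted p = 1.66e-05, and 0.344 with an estimated correlation). MHC class II genes were lower in 10 of 14 cases and higher in 0, also adjusted over the list alone, with H2-DMa 2.60-fold and H2-DMb1 2.33-fold lower (adjusted p = 2.88e-05, and 0.144 with an estimated correlation). Genes of the unfolded protein response were lower in 11 of 19 cases and higher in 0 (13 and 0 adjusted over the list alone), with Edem1 1.43-fold and Hspa5, the chaperone BiP, 1.39-fold lower (adjusted p = 1.91e-04, and 0.284 with an estimated correlation). Known IL-4 and STAT6 target genes were lower in 13 of 18 cases and higher in 3, also adjusted over the list alone (adjusted p = 6.36e-06, and 0.144 with an estimated correlation). Cell cycle genes were higher in 16 of 31 cases and lower in 1 (17 and 1 adjusted over the list alone; adjusted p = 0.0137, and 0.543 with an estimated correlation). The counts of higher and lower genes with slide as a block were 26 and 0 for interferon, 14 and 1 for mature B cell, 15 and 0 for cholesterol, 1 and 8 for MHC class II, 1 and 9 for unfolded protein response, 3 and 13 for known target and 12 and 1 for cell cycle genes. Xbp1 was 3.68-fold lower and Cd80 6.17-fold higher in knockout cells.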

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

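The hypoxia list, the scan of chromosome 1 and the use of slide tests to weigh causes in this part were chosen after the results were seen. The test around Stat6, its version with slide as a block and the comparison with other groupings were planned before.

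Differences between the genotypes in the IL-4 response were picked out because the interaction test passed. They comprise 1756 genes, among them the fixed genes Il4ra (log2 difference 3.17), Ighg1 (2.59, and 1.38 by its second probe) and Ighe (3.96). Among genes with symbols that were well above background in at least 3 of the 4 groups, the largest higher wild-type responses were those of Thy1 (9.49), Htr7 (7.09), Cish (6.35), Il5ra (6.19) and Ndrg2 (6.09). The largest lower ones among them, with a more negative change in wild type than in the knockout, were those of Ccr6 (-6.47), Csf2 (-6.06), Cd5l (-5.71), Itln1 (-5.70) and Nid1 (-5.47). Thy1, Csf2, Cd5l and Itln1 were not well above background on any array of 1 group, so their differences and their order are uncertain. The value for Ndrg2 includes a higher level in knockout than in wild-type controls, which did not pass within slide 1. The counts were set against other groupings of the same arrays. With 3 arrays against 3 only 10 groupings exist, so no share under 0.05 is possible. The real grouping alone (1 of 10) reached its count in the wild-type response (2089 genes, highest other 0), in the knockout response (1 of 10; 580, highest other 77), between controls (1 of 10; 194, highest other 0) and with IL-4 (1 of 10; 1597, highest other 0). For the interaction 2 of 100 groupings reached 1756 genes, the real one included. The other gave 1838 and kept the wild-type IL-4 arrays together as a group while mixing the rest, and a further grouping of that kind gave 1391, so the count reflects mainly how far the wild-type IL-4 arrays stand apart.

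The first pattern weighed is that genes of the hypoxia response were higher in knockout controls: 26 of 38 were higher and 0 lower (34 and 0 adjusted over the list alone), with P4ha2 14.7-fold, Egln3 9.10-fold and Bnip3 5.76-fold higher, and the list had an adjusted p of 8.41e-20, or 0.169 with an estimated correlation. Slide alone does not account for it, because the median within slide 1 was 1.08 against 1.29 over all arrays, although only 1 gene passed there. A state of single cultures, such as low oxygen, could account for it: knockout IL-4 array 3 differed from arrays 1 and 2 along the same genes (r = 0.556 across genes, 0.525 without the list, genes not being independent replicates), with list means of 0.97 against -0.65 and -0.28. Genotype stays open. The list mean of 5 of 6 knockout arrays lay above the highest wild-type array, but the knockout controls among them had defined the pattern. With IL-4, 7 of 38 genes were higher in the knockout and 4 lower (camera adjusted p = 0.354). The median was then 0.48, and -0.06 with slide as a block. That blocked value rests on knockout control 3 against controls 1 and 2. The list mean was highest in control 3 (1.30, against 0.44 and 1.07), so the block also removes this difference between cultures and cannot bear on genotype. These arrays cannot separate genotype from culture.

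The second pattern is that genes differing between the genotypes without IL-4 lie close together. Around Stat6 the share was raised (exact p = 8.95e-05), and on chromosome 1 from 130 to 140 Mb 32 of 101 genes passed (31.7%, adjusted p over all bins 2.02e-05), among them Ctse (8.49-fold lower) and Rnpep (3.11-fold higher). A chromosome segment kept from the strain in which the gene was targeted could explain the region around Stat6. The region on chromosome 1 lies on another chromosome and would need a separate segment. If such differences did not depend on IL-4, they would keep their sign with IL-4. On chromosome 1, 25 of 32 genes passed with the same sign with IL-4, against 538 of 1878 elsewhere (Fisher exact p = 1.33e-08). Near Stat6 only 13 of 30 did (Fisher exact p = 0.107), so this was not seen there. Slide alone does not account for either region: with slide as a block and all genes tested again, the share was still raised near Stat6 (11 of 122 genes against 396 of 16200, exact p = 2.38e-04) and on chromosome 1 (19 of 101 genes, adjusted p over all bins 1.58e-09). Whether strain variants under single probes add to it stays open. A share of 0.385 of other probes (10 of 26) passed with the same sign, and 21 of 26 had the same sign. The genes had been picked because their brightest kept probe passed, so a low share among the other probes cannot decide it.

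The third pattern is that IL-4 changed 580 genes in cells without STAT6. The count depends on the processing: it was 226 with normexp background correction, and also far lower in the authors' values. Slide alone would not favour genes of the wild-type response, which was measured within slide 1, yet 327 genes changed in the same direction in both genotypes, 8.45 times the 38.7 for independent lists, against 44 in opposite directions (34.8 for independent lists). For the 209 genes outside the wild-type response slide stays open: within slide 2, 85.2% of them passed the adjusted p, but they had been chosen by a test that shares these arrays, and the value rests on knockout control 3 alone. The state of single cultures stays open too, since 17 of 38 genes of the hypoxia list, raised in knockout controls, fell in the knockout response and 2 rose (25 and 2 adjusted over the list alone), with a median of -0.85 (adjusted p = 3.95e-06, and 0.352 with an estimated correlation). A response to IL-4 through other signals than STAT6 may be present, but its size is uncertain.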

How the results depend on the processing

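Leaving out knockout control 3 and knockout IL-4 array 3 together was chosen after the results were seen; the other alternatives were chosen before. Of 512 results for named genes, 383 kept direction and side of the threshold under the alternatives run for them, as did 73 of 125 list results (not all were run for each, and with probes required on all 12 arrays 419 and 115 were compared); directions were compared only where a result passed.

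In the order wild-type response, knockout response, interaction, controls and with IL-4, the counts were 1181, 226, 1032, 100 and 883 with normexp background correction; 1262, 261, 1053, 105 and 914 in the authors' values; 1353, 359, 1161, 126 and 964 with probes required on all 12 arrays, where fewer genes were tested; and 9428, 6969, 7388, 1929 and 8431 without a fold minimum. The cause was not tested for normexp and the authors' values. With quantile scaling they were 2081, 563, 1776, 198 and 1595. With a replicate block they were 2090, 585, 1747, 189 and 1595, where deviations of same-number samples correlated over 0.1 in 2 of 18 pairs, both in the knockout (0.316 and 0.392), so pairing there stays open. The count between controls was also 83 without a filter, 81 with a slide block and 69 with both blocks; the cause was not tested.

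Leaving out single arrays gave 2074 to 2152, 544 to 663, 1669 to 1941, 77 to 331 and 1589 to 1674 genes. The 77 came without wild-type control 3 and the 331 without knockout control 1, and fewer samples enter each. Without both arrays 3 of the knockout the knockout response had 668 genes. Stat6 ranged from -1.98 to -1.89 between controls. Of list shifts 29 passed, 29 to 33 without single arrays, 28 with quantile and 35 with median scaling, 37 with normexp, 42 without a filter, 29 to 32 under the other settings, and 0 with an estimated correlation, which widens the test.

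The odds ratio near Stat6 was 1.17 with IL-4, where 51.1% of genes elsewhere passed, against 11.6% without IL-4. Any excess near Stat6 is harder to see against that share, and the cause was not tested. Reversed were Fn1 with IL-4 under the slide block (-0.045) and Ighg1 (ENSMUST00000103420) in the knockout response in the authors' values (-0.19, adjusted p = 0.0401), where its second probe also fell in the scanner files (-0.27); the cause was not tested. Depth limits dim genes: 40.7% to 44.0% of spots were well above background.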

Other observations

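The list of ATF4 and amino acid deprivation genes was chosen after the results were seen, and no explanation was tested for it. IL-4 raised it in both genotypes: 24 of 25 genes rose and 0 fell in wild-type cells (25 and 0 adjusted over the list alone), and 23 rose and 0 fell in knockout cells, also adjusted over the list alone. The median log2 change was 1.44 in wild-type and 1.17 in knockout cells, and 1.03 within slide 2. The adjusted p over the 2 added lists was 9.46e-15 and 1.96e-14, and 0.0498 and 0.0523 with an estimated correlation. By the interaction the wild-type response was higher for 11 of 25 genes and lower for 3 (camera adjusted p = 6.83e-04, and 0.414 with an estimated correlation). With IL-4, 17 of 25 genes were lower in the knockout and 3 higher (camera adjusted p = 1.28e-04, and 0.396 with an estimated correlation). Cth, an enzyme of cysteine synthesis, rose 4.73-fold in wild-type and 3.67-fold in knockout cells, Asns, asparagine synthetase, 2.54-fold and 2.25-fold, and Mthfd2, of mitochondrial folate metabolism, 2.17-fold and 2.52-fold. Atf5, a transcription factor of this response, rose 6.72-fold and 1.76-fold, and Vldlr, a lipoprotein receptor, 6.92-fold in wild type, with an adjusted p of 0.925 in the knockout and an interaction of 2.74 (adjusted p = 0.00179).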
